A study of Rattus norvegicus with 18 samples.

How the data were processed

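Bone marrow mesenchymal stem cells (BMSC) from Sprague-Dawley rats on a normal diet (ND) or a high-fat diet (HFD) for 1, 2 or 4 months were measured as total RNA on 18 Affymetrix rat expression arrays, 3 per diet and feeding time. Per the labels, the cells came from direct plating of whole marrow. The labels of the samples give passage 3 and the series description gives passage 1, and this difference could not be settled. The deposited values are probe set intensity values on a linear scale, and the authors name RMA, with no version, as the summary method. The labels name no scan date, batch or pairing.

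The table held 31099 probe sets, 57 of them array controls, with values from 2.52 to 9915. Log2 was taken of each deposited intensity, with no added constant. The column of ND 1-month replicate 1 stood 1343 rows above its probe sets. All 20 windows of 500 rows lined up best with the mean of the other arrays at that offset, with correlations between 0.977 and 0.991. Its correlation with the mean of the other arrays was 0.0909 as deposited and 0.990 after the move, and the moved values were used. The first 1343 probe sets have no value on that array, 1066 of them among the tested ones.

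Gene names came from the platform annotation: 20832 probe sets had 1 symbol, 436 had several and 9831 had none. Gene identifiers were looked up in the RefSeq gene table of the GRCr8 assembly, which held those of 20764 probe sets. Controls were left out, and so were the dimmest 30% of the other probe sets by mean log2 over all arrays, at or below 3.22 log2 or 9.34 in linear intensity. That left 21729 tested probe sets and 11446 named genes, each represented by its brightest tested probe set. The number of arrays per group, 3, limits the precision.

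A linear model with 1 mean per group was fitted to all arrays in limma 3.58.1 (R 4.3.3) with default moderation. It had 12 residual degrees of freedom, 2.43 prior degrees of freedom and a median residual SD of 0.21 log2 units. The comparisons were HFD minus ND at each feeding time and averaged over the 3 times, an F test of whether the diet effect differs between times, and 4 minus 1 month within each diet. The tests are two-sided, and a probe set passed at a Benjamini-Hochberg adjusted p under 0.05 over the tested probe sets. The model, the filter, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

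Of the 38 fixed gene lists, 36 had at least 5 tested genes and were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Each list was also tested with camera at a correlation estimated from the arrays, with fry and with camera on ranks. Counts adjusted over the list alone stand beside those adjusted over all tested probe sets. The lists include markers of other cells that marrow plating can carry along, such as macrophages.

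Named genes for each diet comparison were the 12 largest rises and 12 largest falls among genes that passed with no overlap between the compared arrays, or with the same sign at all 3 times for the average. Where none passed, they were the 5 highest and 5 lowest by moderated t. For 4 minus 1 month within a diet the number was 8 each way, and for the F test it was the 6 smallest adjusted p. Up to 4 members with the largest absolute moderated t were taken from each described list, and where space was short fewer were printed from the top of each order. The pairs 2 minus 1 and 4 minus 2 months within HFD followed the same rule as additional comparisons.

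The replicate numbers were checked for pairing. Residuals of arrays with the same number had a mean correlation of -0.0254 over 45 pairs, and 5 of the 18 arrays correlated best with their own number at the same feeding time. The numbers were therefore not treated as pairs, and a fit with the number as a block was kept as an alternative. The procedure was tested on simulated data in 5 runs with 200 changed probe sets each. It recovered 66.2% of them at a 2-fold change and 91% at 4-fold, with a mean of 7.4 false calls. The simulated probe sets varied independently of each other, unlike those on the arrays, so these rates do not carry over to the data.

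The alternatives covered the intensity filter, quantile normalization and median centring, the variance model, array weights, fits of the compared arrays alone, averaging probe sets per gene, probe sets open to cross-hybridization, a minimum change of 1.5-fold, and leaving out each array in turn. Further ones were chosen after seeing the data: the mean of the macrophage list as a covariate, the shifted column as deposited, leaving out both ND 1-month replicate 1 and ND 2-month replicate 3, and leaving out the probe sets with no value on ND 1-month replicate 1. Splits of the same arrays into other groups were fitted in the same way. The p-values measure the spread between arrays, whose origin from separate animals is stated only as 3 per group.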

Results

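The study measured RNA in cultured bone marrow mesenchymal stem cells, the adherent stromal cells of the marrow, from rats that were 6 weeks old at the start. ND was a 100% basal diet. HFD replaced part of it, leaving 60%, with lard at 20% and with sucrose and powdered egg yolk at 10% each. The 6 groups, each diet after 1, 2 and 4 months, held 3 arrays each. Array medians lay between 25.4 and 27.1 in linear intensity and the 75th percentiles between 119 and 132. The 3' minus 5' difference of the beta-actin control probe sets, a measure of RNA degradation, lay between 0.48 and 0.70 log2 units on all arrays. Xist, the RNA of the inactive X chromosome, read 8.31 to 9.58 log2 units and the Y-linked Eif2s3y 1.57 to 2.06 on all 18 arrays.

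Markers of macrophages varied widely between cultures of the same group. The lysosomal protein Cd68 ranged from 4.53 to 10.78 log2 units over the 18 arrays, the leukocyte phosphatase Ptprc from 2.18 to 7.96, and the lysozyme Lyz2 from 8.07 to 12.97. List means take only genes with a value on every array, 25 of the 29 tested macrophage genes. The mean of the macrophage and monocyte list, relative to its average over arrays, was -1.21 ± 2.28 (SD, n = 3) in ND and -0.12 ± 0.79 in HFD at 1 month. At 2 months it was 0.44 ± 1.82 in ND and -1.11 ± 1.16 in HFD, and at 4 months 0.73 ± 0.92 and 1.27 ± 0.16. The first principal component held 38.1% of the variance. Arrays of the same group had a mean correlation of 0.968 over 18 pairs and arrays of different groups 0.962 over 135 pairs, and 7 of the 18 arrays lay closest to an array of their own group.

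**Figure D1:**
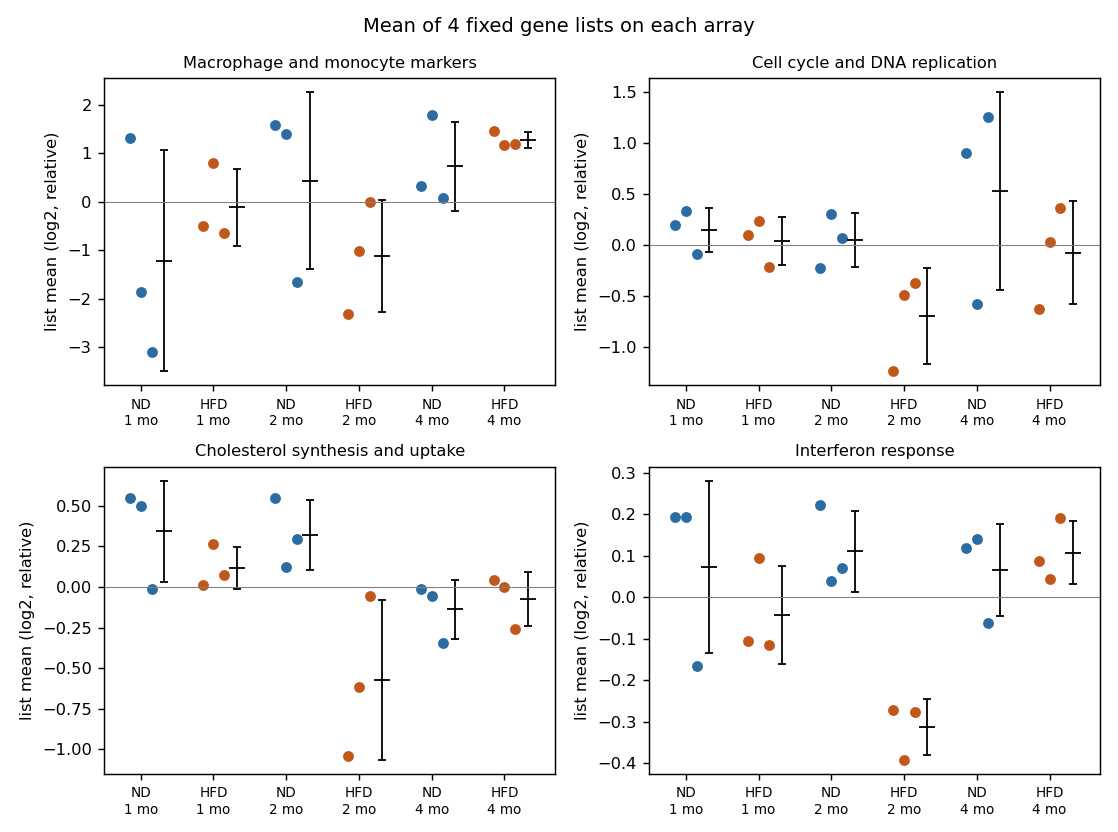
Mean log2 intensity of the macrophage, cell cycle, cholesterol and interferon lists on each array, relative to the list's average over the 18 arrays; points are arrays, blue for ND and orange for HFD, and black bars give the mean ± SD of each group (n = 3). The macrophage list spans the widest range, with a mean of -1.21 in ND at 1 month and 1.27 in HFD at 4 months. The means take only genes with a value on every array: 25 macrophage, 45 cell cycle, 12 cholesterol and 22 interferon genes.

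The first comparison asked what 1 month of HFD changed, and no single gene passed the test. Zic2, a zinc finger transcription factor, had a log2 fold change of 0.61 ± 0.10 (SE, n = 3 per group, adjusted p = 0.0564), Nxnl1, a thioredoxin-like protein, 0.53 ± 0.08 (0.0564), and the signalling protein Chn2 1.07 ± 0.20 (0.0876). Pdxdc1 stood at -1.46 ± 0.24 (0.0564). Pias1, a SUMO ligase, stood at -0.45 ± 0.07 (0.0564), the RNA helicase Ddx6 at -0.57 ± 0.10 (0.0564), and the splicing factors Khsrp and Srrm2 at -0.74 ± 0.13 (0.0564) and -0.55 ± 0.10 (0.0566). With the probe sets of a gene averaged, Chn2 stood at 0.68, Khsrp at -0.49 and Srrm2 at -0.32. In limma 0 of 21729 probe sets passed, with a lowest adjusted p of 0.0513. At an unadjusted p under 0.05 there were 2124, where chance gives 1086. With array weights 28 passed, with a stricter intensity filter 14 and with the mean of the macrophage list as a covariate 34.

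Macrophage genes were called higher as a group at 1 month. Of the 29 tested members of the macrophage and monocyte list 24 had a positive log2 fold change, with a median of 1.40, and 0 members passed (adjusted p = 1.34e-07 for the list; adjusted p = 0.793 with an estimated correlation). The tetraspanin Cd53 stood at 4.17 ± 1.22, the microglia and macrophage protein Aif1 at 3.76 ± 1.12 and Lyz2 at 2.29 ± 0.91. The shifted ND replicate 1 has no value for 4 of the 29 genes, and Cd53 and Aif1 rest on 2 ND arrays, where Cd53 read 5.78 and 3.70 and Aif1 4.60 and 2.96, the latter below the filter's mean level of 3.22. With its probe sets averaged Aif1 stood at 2.03. Over the 25 genes with a value on every array the median was 1.27. Lyz2 read 12.89 on ND replicate 1 and 8.07 on ND replicate 3, and stood at 3.64 without ND replicate 1 and at 1.23 without ND replicate 3. Senescence-associated secreted factors (21 of 25 positive, median 0.26) and collagens and matrix (25 of 40 positive, median 0.08) were called higher, each at adjusted p = 0.0327 and at adjusted p = 0.793 with an estimated correlation. Their examples were Vegfa, an angiogenic growth factor, at 0.63 ± 0.40, Igfbp3, which binds insulin-like growth factors, at 1.20 ± 0.85, the collagen crosslinking enzyme Lox at 0.30 ± 0.12 and elastin, Eln, at 0.82 ± 0.37. Igfbp3 and Lox have no value on ND replicate 1, so 2 ND arrays stand against 3. Leaving out 1 array gave 0.15 to 1.02 for Vegfa, 0.31 to 2.08 for Igfbp3 and 0.12 to 0.49 for Lox.

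Matrix proteases and their inhibitors (16 of 22 positive, median 0.15) were called higher too, with the macrophage elastase Mmp12 at 3.56 ± 1.11 (2 ND arrays, 5.81 and 4.30) and the protease inhibitor Timp3 at 1.07 ± 0.65. Timp3 stood between 0.57 and 1.74 with 1 array left out, and Mmp12 at 1.90 with the macrophage covariate. So were skeletal and cardiac muscle markers (8 of 9 positive, median 0.21), granulocyte and mast cell markers (7 of 8, median 0.25) and endothelial markers (9 of 9, median 0.16). These lists had adjusted p = 0.0327, and adjusted p = 0.222 with an estimated correlation. No member of the 7 called lists passed, over all probe sets or adjusted over the list alone. With quantile normalization 2 lists were called at 1 month, with no intensity filter 1, and over the genes with a value on every array 3, those of macrophages, granulocytes and endothelium.

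With the mean of the macrophage list as a covariate, 1 of the other 6 lists called at 1 month was still called, collagens and matrix (median 0.18). The macrophage list itself cannot be tested in a fit with its own mean. Senescence-associated secreted factors then had a median of 0.09 (adjusted p = 0.376), and proteases, skeletal and cardiac muscle, granulocyte and endothelial markers were not called either. In that fit 6 further lists were called at the preset correlation. Hypoxia targets (median -0.59, adjusted p = 0.00229), glycolysis (median -0.39, adjusted p = 0.0031) and cholesterol synthesis (median -0.43, adjusted p = 0.0027) were called lower, and TGF-beta, smooth muscle and erythroid lists higher. No estimated correlation was computed for the fit with the covariate.

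At 2 months 359 named genes passed, 149 higher and 210 lower in HFD. Sfrp1, a secreted WNT antagonist, fell by 3.90 ± 0.47 log2 units (SE, n = 3 per group, adjusted p = 0.00418), from 10.82 ± 0.40 (SD) in ND to 6.92 ± 0.85 in HFD. Cxcl12, the chemokine with which marrow stroma retains haematopoietic cells, fell by 3.20 ± 0.47 (0.00922), from 12.13 ± 0.54 to 8.94 ± 0.68. Haptoglobin, Hp, an acute-phase haemoglobin-binding protein, fell by 3.34 ± 0.46 (0.00623). The desmosome protein Pkp2 rose by 2.95 ± 0.48 (0.0104), and Casq2, the calcium-binding protein of the cardiac sarcoplasmic reticulum, rose by 2.50 ± 0.40 (0.00965).

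Among the other rises were the transporter Flvcr2 (2.98 ± 0.55), the growth factor Nrg1 (2.61 ± 0.58, or 1.63 with its probe sets averaged), the LIM protein Csrp2 (2.60 ± 0.55), skeletal muscle actin Acta1 (2.58 ± 0.57), the LIM protein Fhl1 (2.46 ± 0.56) and Enpp1 (2.35 ± 0.39), which makes the mineralization inhibitor pyrophosphate. There were further falls. Apelin, Apln, fell by 3.64 ± 0.82, the interleukin-1 receptor antagonist Il1rn by 3.25 ± 0.55 and the collagen Col14a1 by 3.23 ± 0.57. The angiogenic factors Angpt1 and Vegfd fell by 2.90 ± 0.58 and 2.61 ± 0.45. Complement C1s fell by 2.48 ± 0.37, and the lipopolysaccharide-binding protein Lbp fell by 2.48 ± 0.51. In the GRCr8 assembly Sfrp1 (gene 84402) lies on chromosome 16 from 75278325 to 75316736, Cxcl12 (gene 24772) on chromosome 4 from 152060781 to 152073628 and Hp (gene 24464) on chromosome 19 from 54449151 to 54453701.

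**Figure D2:**
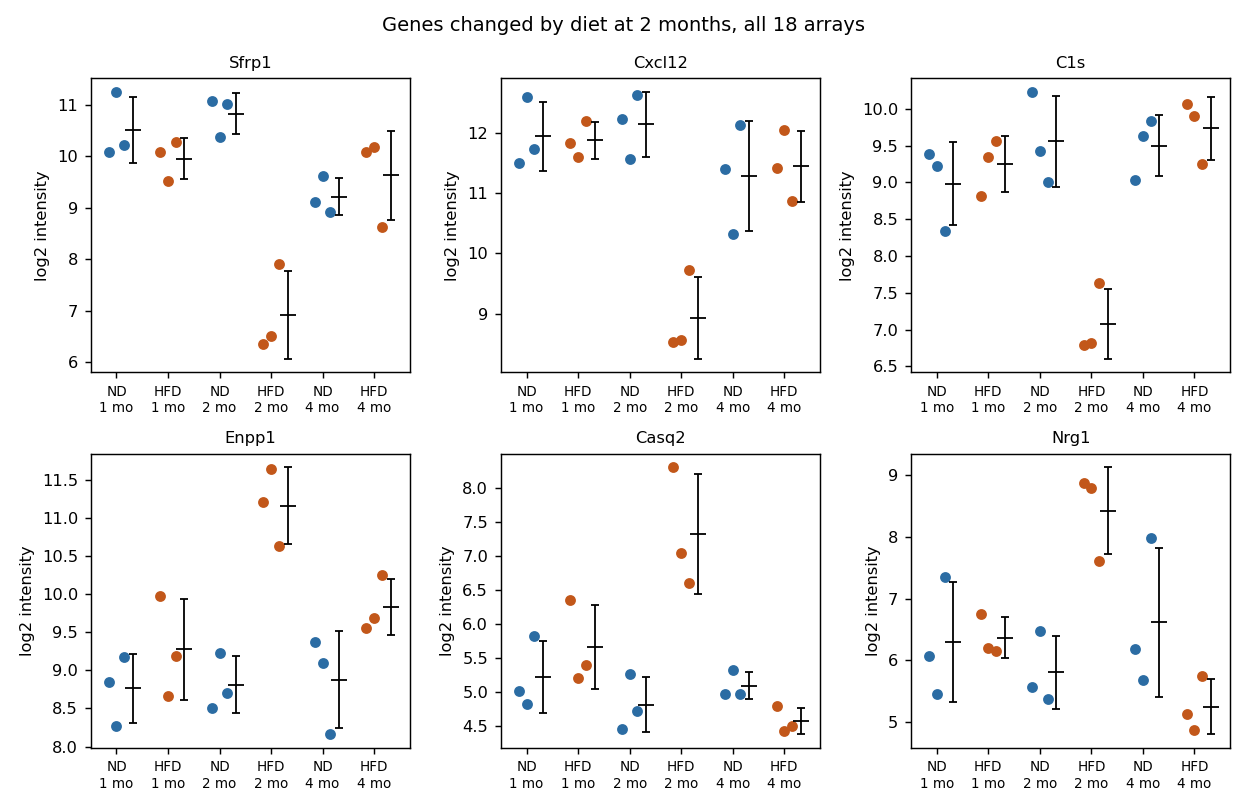
Log2 intensity of genes that passed the test at 2 months, on each array of the 6 groups; points are arrays, blue for ND and orange for HFD, and black bars give the mean ± SD (n = 3). Sfrp1 stands at 6.92 in HFD at 2 months and at 10.82 in ND at the same time.

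The cholesterol, fatty acid synthesis and adipogenic lists were called lower at 2 months of HFD. All 20 tested cholesterol synthesis and uptake genes had negative log2 fold changes, with a median of -0.94. Of these 6 fell, 0 rose and 14 did not pass, and 19 fell when adjusted over the list alone (list adjusted p = 4.34e-12; adjusted p = 0.606 with an estimated correlation). Insig1, which retains the sterol sensor in the endoplasmic reticulum, fell by 1.59 ± 0.31, squalene epoxidase Sqle by 1.33 ± 0.28 and squalene synthase Fdft1 by 1.24 ± 0.26. Of 21 fatty acid and triglyceride synthesis genes 2 fell and 19 did not pass, and 10 fell and 1 rose adjusted over the list alone (median -0.47, adjusted p = 0.00335; adjusted p = 0.641 with an estimated correlation). The desaturase Scd fell by 1.90 ± 0.47 and the desaturase Fads1 fell by 1.69 ± 0.41. Of 20 adipogenic genes 2 fell and 18 did not pass, 4 falling adjusted over the list alone (median -0.71, adjusted p = 0.00617; adjusted p = 0.641 with an estimated correlation). These were the adipogenic transcription factors Cebpa, which fell by 1.65 ± 0.38, and Cebpd, which fell by 1.24 ± 0.27.

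The interferon response and cell cycle lists were called lower as well. Of 26 interferon genes 4 fell and 22 did not pass, with 9 falling and 1 rising adjusted over the list alone (median -0.45, list adjusted p = 0.000161; adjusted p = 0.563 with an estimated correlation). The immunoproteasome subunit Psmb9 fell by 1.94 ± 0.30, the GTPase Igtp by 1.09 ± 0.26 (with its probe sets averaged, -0.56 at adjusted p = 0.0795), the signalling factor Stat2 by 0.85 ± 0.16 and the antiviral membrane protein Ifitm3 by 0.56 ± 0.10. In the cell cycle and DNA replication list 47 of 48 genes had a negative log2 fold change (median -0.74), and 0 passed, also when adjusted over the list alone. That list's adjusted p was 1.06e-06, and adjusted p = 0.662 with an estimated correlation. The proliferation marker Mki67 stood at -1.45 ± 0.44 (adjusted p = 0.0872) and the mitotic cyclin Ccnb2 at -1.24 ± 0.44 (0.136). Without HFD replicate 1 Mki67 stood at -0.90.

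Glycolysis, hypoxia, antioxidant and oxidative phosphorylation lists were called lower too. Glycolysis genes had 18 of 18 negative values, with 1 fall, 17 not passing and 2 falls adjusted over the list alone (median -0.59, adjusted p = 0.00198). The lactate transporter Slc16a1 was the one that fell, by 0.60 ± 0.15. Among 21 hypoxia targets 2 fell and 19 did not pass, with 4 falls and 1 rise adjusted over the list alone (median -0.66, adjusted p = 0.00358): the stress-response gene Ndrg1 fell by 1.49 ± 0.34 and the oxidoreductase Ero1a by 1.22 ± 0.24. Of 28 NRF2 and antioxidant genes catalase, Cat, fell by 0.62 ± 0.15 and 27 did not pass (median -0.27, adjusted p = 0.0178), with 1 rise and 1 fall adjusted over the list alone. Nqo1 of that list did not pass but was higher in HFD, at 10.9, 10.53 and 10.37 log2 units against 9.2, 8.37 and 9.85 in ND. Oxidative phosphorylation had 26 of 28 negative values (median -0.11, adjusted p = 0.00554; Ndufs1, a complex I subunit, at -0.34 ± 0.10), with 0 members passing in either way. These 4 lists had adjusted p = 0.662 with an estimated correlation. Ribosomal proteins had 25 of 26 negative values and 0 passing in either way (median -0.12, adjusted p = 0.00554; adjusted p = 0.717 with an estimated correlation; Rps9 at -0.26 ± 0.11, and between -0.40 and -0.17 with 1 array left out).

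Smooth muscle, skeletal muscle, TGF-beta and osteogenic lists were called higher at 2 months. Of 19 smooth muscle genes Myocd, a transcriptional coactivator of that lineage, rose by 1.98 ± 0.45 and 18 did not pass, with 1 rise adjusted over the list alone (median 0.22, adjusted p = 0.00198; adjusted p = 0.662 with an estimated correlation). Of 9 skeletal and cardiac muscle markers Acta1 rose and 8 did not pass, with 2 rises adjusted over the list alone (median 0.27, adjusted p = 0.0252; adjusted p = 0.563 with an estimated correlation). Of 26 TGF-beta and BMP genes the SMAD repressor Skil rose by 0.97 ± 0.24 and 25 did not pass. Adjusted over the list alone 3 rose and 3 fell (median 0.42, list adjusted p = 0.00808, and adjusted p = 0.662 with an estimated correlation). Smad3 of that list did not pass but was lower in HFD, at 6.95, 6.48 and 7.44 log2 units against 8.44, 7.7 and 8.26 in ND. None of 13 osteogenic genes passed, with 4 rises and 1 fall adjusted over the list alone (median 0.58, adjusted p = 0.0252; adjusted p = 0.641 with an estimated correlation). The bone matrix proteins osteopontin, Spp1, and bone sialoprotein, Ibsp, stood at 1.24 ± 0.37 (adjusted p = 0.0895) and 2.62 ± 0.84 (0.106). The 9 osteogenic genes with a value on every array, which leave out these genes, had a mean relative level of 0.05 ± 0.73 (SD, n = 3) in ND and 0.05 ± 0.29 in HFD at 2 months, with ND replicate 3 highest at 0.88, and were not called (median 0.17, adjusted p = 0.39).

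The macrophage list was called lower in the same comparison. Of the 29 genes 27 had negative values and 0 passed, also adjusted over the list alone (median -1.59, list adjusted p = 0.00808; adjusted p = 0.717 with an estimated correlation). The macrophage surface receptor Adgre1 stood at -3.36 ± 1.03 (adjusted p = 0.0891) and Aif1 at -2.04 ± 1.00, between -3.28 and -1.24 with 1 array left out and at -1.1 with its probe sets averaged. With the mean of the macrophage list as a covariate, 7 of the other 14 lists called at 2 months were still called: cholesterol synthesis (adjusted p = 6.41e-10), cell cycle, adipogenic genes, interferon response, fatty acid synthesis, oxidative phosphorylation and ribosomal proteins. In that fit the median was -0.20 for hypoxia targets (adjusted p = 0.197), -0.25 for glycolysis (0.204), -0.14 for NRF2 genes (0.208), 0.19 for osteogenic genes (0.33) and 0.12 for smooth muscle genes (0.16). It was 0.25 for skeletal and cardiac muscle (adjusted p = 0.0775) and 0.40 for TGF-beta and BMP genes (0.197). Over the genes with a value on every array fatty acid synthesis (adjusted p = 0.0724), NRF2 (0.132), TGF-beta (0.105) and skeletal muscle lists (0.364) were not called. The genes left out have values on all 2-month arrays, so this setting shortens the lists and tests no gap in the arrays compared.

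At 2 months 552 probe sets passed in limma, 269 higher and 283 lower in HFD, and they stand for the 359 named genes. Of the 552, 250 changed at least 2-fold and 66 at least 4-fold, with a median absolute log2 fold change of 0.93. The share of higher calls was 48.7%, with quantile normalization 59.7% of 526 and with median centring 67.4% of 565. The count was 48 without ND 2-month replicate 1, 207 without ND replicate 2, 86 without HFD replicate 1, 71 without HFD replicate 2, 1261 without HFD replicate 3, in a fit of the 6 compared arrays alone 2 and with array weights 4330. It was 355 without HFD 4-month replicate 1, 346 without HFD 4-month replicate 2 and 1319 without ND 1-month replicate 1 and ND 2-month replicate 3.

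After 4 months of HFD the cell cycle list was called lower, and no single gene passed. All 48 cell cycle and DNA replication genes had negative log2 fold changes, with a median of -0.65, and 0 passed, also adjusted over the list alone (list adjusted p = 2.17e-13; adjusted p = 0.932 with an estimated correlation). The mitotic transcription factor Foxm1 stood at -0.63 ± 0.31 (SE, n = 3 per group), the spindle checkpoint kinase Bub1b at -0.79 ± 0.39 and the kinesin Kif23 at -0.87 ± 0.43. Without ND replicate 2 they stood at -1.05, -1.32 and -1.52, and without ND replicate 3 at -0.32, -0.41 and -0.47. Over its 45 genes with a value on every array the list's mean relative level was 0.91, -0.57 and 1.26 on the ND arrays (SD 0.97). On the HFD arrays it was -0.63, 0.03 and 0.37, so ND replicate 2 lay below 2 of the 3 HFD arrays. Macrophage markers were called higher, with 26 of 29 positive values and a median of 0.41 (adjusted p = 0.0311; adjusted p = 0.932 with an estimated correlation), among them the class II antigen presentation genes RT1-Db1 at 0.61 ± 0.33 and RT1-Da at 0.52 ± 0.31.

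Fatty acid oxidation and PPAR targets had 19 of 24 positive values at 4 months (median 0.11, adjusted p = 0.046), such as Acadm, a mitochondrial acyl-CoA dehydrogenase, at 0.24 ± 0.13, and the nuclear receptor Ppard at 0.23 ± 0.13. Ribosomal proteins had 22 of 26 positive values (median 0.07, adjusted p = 0.0365), with Rpl28 at -0.34 ± 0.23 and Rpl6 at 0.13 ± 0.09. Acadm stood at 0.12 without ND replicate 3, Ppard at 0.15 without HFD replicate 1, Rpl28 at -0.21 without ND replicate 2 and Rpl6 at 0.08 with quantile normalization. Over the arrays with a value Rpl28 read 3.46 to 4.36 log2 units, near the filter's mean level of 3.22, and Rpl6 11.91 to 12.29. Both the fatty acid oxidation and ribosomal lists had adjusted p = 0.932 with an estimated correlation, and 0 members of either or of the macrophage list passed, also adjusted over the list alone. The strongest single genes, none of which passed (adjusted p = 0.999), were the transcription factor Pbx2 at 0.50 ± 0.10, Ccdc134 at -0.87 ± 0.19 and the splicing factor Cwc25 at -1.62 ± 0.36. The mast cell receptor Milr1 also stood among them, reading 6.30, 5.17 and 5.59 log2 units in HFD and 2.31, 2.80 and 2.06 in ND, below the filter's mean level of 3.22, so no fold is given. In limma 0 probe sets passed, with 811 at an unadjusted p under 0.05 where chance gives 1086. With no intensity filter 1 list was called at 4 months, with quantile normalization 2, over the genes with a value on every array 1, that of the cell cycle, and with the macrophage covariate 2 of the other 3, the cell cycle and fatty acid oxidation.

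**Figure D3:**
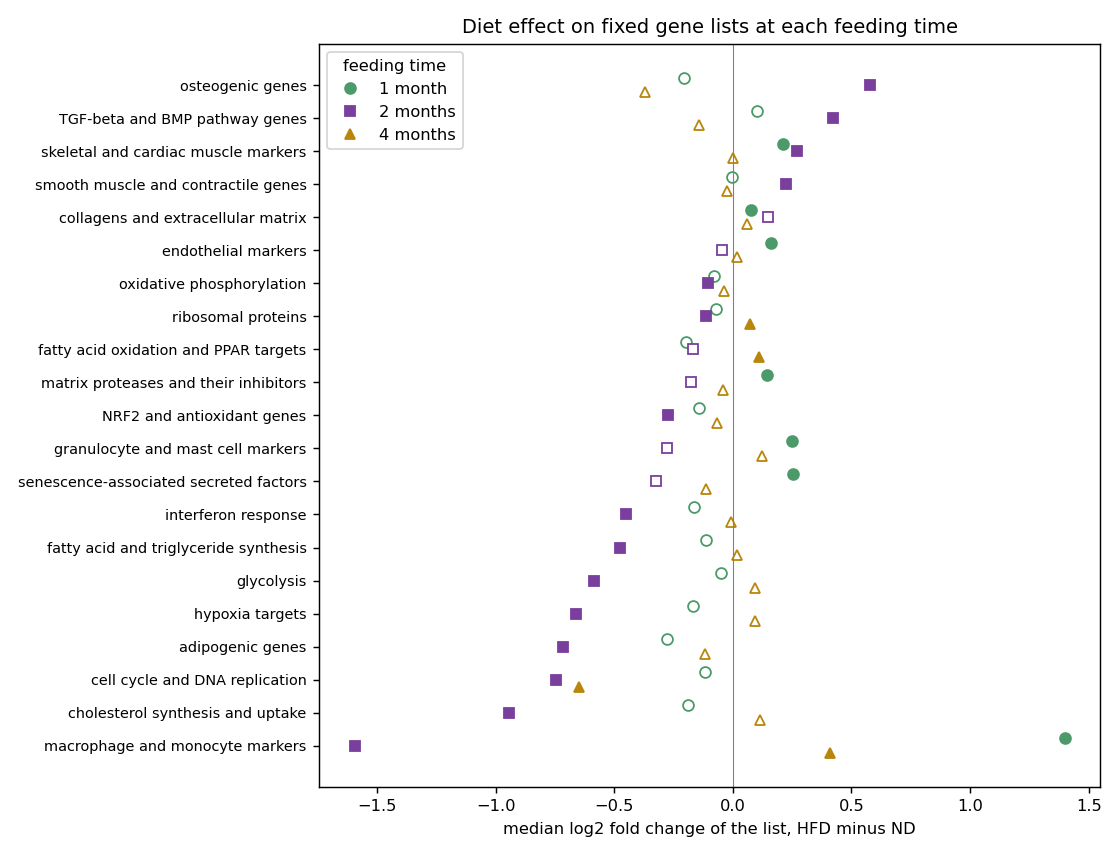
Median log2 fold change, HFD minus ND, of the genes of each list called at 1 or more of the feeding times; circles are 1 month, squares 2 months and triangles 4 months, filled where the list was called and open where it was not. The macrophage list stands at 1.40, -1.59 and 0.41 at 1, 2 and 4 months, and the cell cycle list at -0.74 at 2 and -0.65 at 4 months.

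Averaged over the 3 feeding times, 612 probe sets passed in limma. The times weigh equally, so a gene that changed mainly at 1 of them can pass. Enpp1 rose by 1.27 ± 0.22 log2 units (SE, n = 9 per diet, adjusted p = 0.0179), the protease-like Prss35 by 1.94 ± 0.44 (0.0378), Csrp2 by 1.40 ± 0.32 (0.0382) and the thyroid hormone receptor Thrb by 0.72 ± 0.16 (0.0335). Vegfd, a growth factor of lymphatic vessels, fell by 1.53 ± 0.26 (0.0156), with -1.54, -2.61 and -0.44 at 1, 2 and 4 months. Haptoglobin, Hp, fell by 1.30 ± 0.26, the iron exporter Slc40a1 by 0.83 ± 0.21, the matrix proteoglycan Vcan by 0.75 ± 0.15, the cytokine receptor subunit Il6st by 0.71 ± 0.17 and the preadipocyte factor Zfp423 by 0.67 ± 0.14. The splicing factor Cwc25 fell by 1.05 ± 0.21, Psmb9 by 0.89 ± 0.17 and Pdxdc1 by 0.82 ± 0.14, while the serpin Serpinb6b rose by 0.88 ± 0.14. Hp read 5.14, 5.86 and 5.28 log2 units in HFD at 2 months against 9.51, 8.99 and 7.79 in ND. At 1 month it read 9.03, 7.79 and 7.9 in HFD against 8.08, 8.16 and 8.6 in ND. Zfp423 has 8 ND arrays, since ND 1-month replicate 1 lacks it. With the probe sets of a gene averaged, Zfp423 stood at -0.05 (adjusted p = 0.853), Thrb at 0.44 (0.17) and Sc5d at -0.29 (0.107).

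All 48 cell cycle genes had negative averages with 0 passing in either way (median -0.49, list adjusted p = 4.84e-07; adjusted p = 0.731 with an estimated correlation), with Ccnb2 at -0.80 ± 0.25. All 20 cholesterol genes were negative too. The sterol desaturase Sc5d fell by 0.50 ± 0.12, 19 did not pass, and 4 fell adjusted over the list alone (median -0.34, adjusted p = 4.52e-05; adjusted p = 0.731 with an estimated correlation). Oxidative phosphorylation had 27 of 28 negative values and 0 passing in either way (median -0.09, adjusted p = 0.00945; adjusted p = 0.731 with an estimated correlation), with Ndufs1 at -0.22 ± 0.06 (-0.13 with quantile normalization). Of 9 skeletal and cardiac muscle markers 0 passed and 2 rose adjusted over the list alone (median 0.15, adjusted p = 0.0283; adjusted p = 0.51 with an estimated correlation), the troponin Tnni2, with 8 ND arrays, standing at 0.26 ± 0.07. The muscle list was not called over its 6 genes with a value on every array (adjusted p = 0.257). With the macrophage covariate all 4 lists were still called and 7 more at the preset correlation: adipogenic, interferon, glycolysis and hypoxia lists lower, and matrix, smooth muscle and TGF-beta lists higher, with adjusted p up to 0.047.

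Of the 612 probe sets 215 were higher and 397 lower, for 460 named genes. Among them 575 had the same sign at all 3 times, the median absolute log2 fold change was 0.38, and 17 changed at least 2-fold. The average contains the 2-month arrays, and 216 of its probe sets were also called at 2 months, all in the same direction. The share of higher calls was 35.1%, with quantile normalization 57.0% of 286 and with median centring 70.1% of 462. The count was 3317 with array weights, 1305 with the macrophage covariate and 101 at a minimum of 1.5-fold. The count was 117 without ND 4-month replicate 1, 1053 without ND 4-month replicate 2 and 125 without HFD 1-month replicate 3. It was 180, 325 and 270 without HFD 4-month replicates 1, 2 and 3, 207 and 226 without HFD 2-month replicates 1 and 2, 228 and 270 without ND 2-month replicates 1 and 2, 300 without HFD 1-month replicate 1, and 357 and 196 without ND 1-month replicates 1 and 2.

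Whether the diet effect differed between the feeding times was asked with an F test. Its smallest adjusted p belonged to Sfrp1 and Ccdc71l (both 0.132), followed by the RNA-binding Rbm11, complement C1r and the inositol phosphate kinase Ppip5k1 (each 0.215) and C1s (0.237). The diet effect on Sfrp1 was -0.56 at 1 month, -3.90 at 2 months and 0.41 at 4 months. In limma 0 of 21729 probe sets passed this test, with 1474 at an unadjusted p under 0.05 where chance gives 1086. The changes that passed at 2 months are thus not shown to differ from those at 1 or 4 months. Of the 552 probe sets called at 2 months, 475 (86.1%) had the same sign at 1 month and 323 (58.5%) at 4 months. Their median log2 fold change in the direction of the call was 0.24 at 1 month and 0.05 at 4 months. Without HFD 2-month replicate 3 the F test passed 32 probe sets, and with array weights 115.

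Over all 11446 named genes the log2 fold changes at 1 and 2 months correlated at Pearson's r = 0.11 (Spearman's rho = 0.33), those at 1 and 4 months at r = 0.21 (rho = 0.23) and those at 2 and 4 months at r = -0.0046 (rho = 0.081). The shares of genes with the same sign were 64.6%, 58.9% and 54.0%. The jackknife standard errors of r over arrays were 0.535, 0.198 and 0.15, so the order of these values is not resolved. These are correlations across genes, which are not independent replicates, and the 3 comparisons share no arrays.

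Within ND, 4 minus 1 month asked what changed with age and time on the basal diet. The macrophage list was called higher at 4 months, with positive values in all 29 tested genes, a median log2 fold change of 2.24, 0 passing and 3 rising adjusted over the list alone (list adjusted p = 5.29e-13; adjusted p = 0.526 with an estimated correlation). Cd53 stood at 5.41 ± 1.22 (SE), with 2 arrays at 1 month (5.78 and 3.70) against 3 at 4 months. Over the 25 macrophage genes with a value on every array the median was 2.22. Of 35 NF-kB and inflammatory genes 28 were positive (median 0.55, adjusted p = 1.95e-06; adjusted p = 0.559 with an estimated correlation), with interleukin-1 beta, Il1b, at 3.40 ± 1.17 and the prostaglandin synthase Ptgs2, with 2 arrays at 1 month, at 1.84 ± 0.58. Ptgs2 stood at 1.06 without ND 1-month replicate 2, and Il1b at 2.13 with the macrophage covariate. All 48 cell cycle genes were positive (median 0.37, adjusted p = 1.09e-06; adjusted p = 0.595 with an estimated correlation), such as the kinesin Kif2c at 0.88 ± 0.45 (0.42 to 1.44 with 1 array left out), and 19 of 20 cholesterol genes were negative (median -0.55, adjusted p = 2.53e-06; adjusted p = 0.595 with an estimated correlation), such as Msmo1, again with 2 arrays at 1 month, at -0.89 ± 0.23. No member of these 3 lists passed, and 1 cholesterol gene fell adjusted over the list alone.

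The other lists called in ND with time went both ways. Senescence-associated secreted factors, unfolded protein response, glycolysis, hypoxia, NRF2, granulocyte and immediate early genes were called higher, and smooth muscle, WNT and fatty acid oxidation genes lower, 14 lists in all, with adjusted p between 0.526 and 0.595 with an estimated correlation. The cystine transporter Slc7a11 stood at 1.55 ± 0.49, the smooth muscle protein Smtn at -0.69 ± 0.18 and the WNT target Axin2 at -0.58 ± 0.14. Of single genes none passed in limma: the axon guidance receptor Sema6a stood at -1.58 ± 0.23 (adjusted p = 0.125), the ephrin receptor Ephb4 at -0.80 ± 0.14 (0.148) and the membrane protein Emp2 at 1.02 ± 0.20 (0.227). The 0 probe sets that passed stand beside 2040 at an unadjusted p under 0.05. Without ND 1-month replicate 1 and ND 2-month replicate 3 together, 139 passed. With the macrophage covariate 5 of the other 13 lists were still called, while NF-kB genes had a median of 0.04 (adjusted p = 0.0675), glycolysis -0.16 (0.348) and hypoxia targets -0.17 (0.348). Over the genes with a value on every array fatty acid oxidation (adjusted p = 0.0752), granulocyte (0.0596) and immediate early genes (0.246) were not called.

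Within HFD, the NF-kB list was called higher and the smooth muscle and matrix lists lower over the same interval. Of 35 NF-kB genes 30 were positive (median 0.50, adjusted p = 1.07e-05), with Il1rn at 2.05 ± 0.55 (SE, n = 3 per group), and of 29 macrophage markers 28 (median 1.16, adjusted p = 1.07e-05), with RT1-Db1 at 0.99 ± 0.33. Of 21 hypoxia targets 20 were positive (median 0.59, adjusted p = 1.18e-05; Ero1a 0.74 ± 0.24) and of 18 glycolysis genes 17 (median 0.50, adjusted p = 1.24e-05; Slc16a1 0.50 ± 0.15). Smooth muscle genes had 18 of 19 negative values (median -0.36, adjusted p = 1.03e-06; the tropomyosin Tpm2 at -0.36 ± 0.09, or -0.60 with its probe sets averaged), with 4 falls and 1 rise adjusted over the list alone. Each of these lists had adjusted p = 0.497 with an estimated correlation, and 0 members passed over all probe sets.

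Matrix genes had 27 of 40 negative values over that interval in HFD (median -0.23, adjusted p = 0.0157; adjusted p = 0.497 with an estimated correlation), with the proteoglycan Lum at -0.91 ± 0.21 and the basement membrane collagen Col4a1 at -1.36 ± 0.36, and 3 falls adjusted over the list alone. Cholesterol genes had 16 of 20 negative values (median -0.30, adjusted p = 0.00722; adjusted p = 0.678 with an estimated correlation), with Msmo1 at -0.64 ± 0.20. In all, 14 lists were called, the others being senescence-associated secreted factors, unfolded protein response, NRF2, immediate early and ribosomal genes higher and fatty acid synthesis and WNT genes lower, with adjusted p between 0.497 and 0.736 with an estimated correlation. Among single genes the signalling protein Chn2 stood at -1.24 ± 0.20 (adjusted p = 0.182), Sema6a at -1.25 ± 0.23 (0.211), the ketone metabolism enzyme Bdh2 at -1.20 ± 0.21 (0.211) and the immediate early factor Junb at 0.84 ± 0.19 (0.335). In limma 0 probe sets passed, with 1721 at an unadjusted p under 0.05, and with array weights 434 passed. With the macrophage covariate 8 of the other 13 lists were still called, while matrix genes had a median of -0.12 (adjusted p = 0.447) and senescence-associated secreted factors 0.14 (0.197). The median of no called list changed sign under quantile normalization or median centring in any of these comparisons, and 6 moved by over 1.5 times. Under centring the median was 0.17 for matrix and 0.25 for endothelial genes at 1 month, and for oxidative phosphorylation -0.03 both at 2 months and in the average. Centring gave ribosomal proteins -0.04 at 2 months. With quantile normalization oxidative phosphorylation stood at -0.07 at 2 months and -0.03 in the average, and ribosomal proteins at 0.04 at 4 months.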

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

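The tests of macrophage content, of an exchange of arrays and of the intensity distribution were chosen only after the results were seen. The differences below compare the diet effect on a gene list between feeding times, as the median over the list of the difference in log2 fold change. Each passed camera at its preset correlation. With an estimated correlation 0 of the 32 passed, the lowest adjusted p being 0.382 for 2 minus 1 month, 0.419 for 4 minus 1 month and 0.657 for 4 minus 2 months, and fry gave lowest adjusted p of 0.377, 0.973 and 0.125. Single arrays that lie apart were not tested for in groups of 3, and the estimated array weights ranged from 0.39 to 2.69.

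Between 1 and 2 months the diet effect moved down in 11 lists and up in 1. The largest shift was that of macrophage markers, at -2.63. It was -0.78 for cholesterol synthesis, -0.61 for the cell cycle, -0.61 for granulocyte and mast cell markers, -0.56 for glycolysis and -0.51 for hypoxia targets. Fatty acid synthesis moved by -0.49, adipogenic genes by -0.43, interferon response by -0.31, NRF2 genes by -0.19 and the unfolded protein response by -0.18. Smooth muscle genes moved by 0.23.

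Between 1 and 4 months the shift was -1.04 for macrophage markers, -0.49 for the cell cycle, -0.43 for senescence-associated secreted factors, -0.24 for matrix proteases, -0.23 for TGF-beta and BMP genes, -0.16 for endothelial markers and -0.094 for the unfolded protein response. It was 0.28 for fatty acid oxidation and 0.14 for ribosomal proteins. Between 2 and 4 months it was 2.02 for macrophage markers, 1.10 for cholesterol synthesis, 0.81 for hypoxia targets, 0.60 for glycolysis, 0.43 for interferon response, 0.43 for adipogenic genes, 0.42 for fatty acid synthesis and 0.19 for ribosomal proteins. It was -0.98 for osteogenic genes, -0.57 for TGF-beta and BMP genes and -0.27 for smooth muscle genes.

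The first pattern weighed is that 7 of 18 arrays lay closest to an array of their own group. The beta-actin 3' minus 5' difference removed 8.89% of the within-group variance, below the 15.0% that 95% of 1000 permuted scores stayed under. RNA quality was thus not shown to be a source by this measure. The same difference of the GAPDH control, 0.01 to 0.15 log2 units over the arrays, was not tested, so RNA quality stays open. The mean of the macrophage list removed 38.3% of the within-group variance, above 26.1% for permuted scores. A differing share of macrophages, a cell that adheres to plastic with stroma, is thus a candidate source. The list's 33 genes stand in no other list, 29 were tested, and the mean takes the 25 with a value on every array. Abundant ones such as Lyz2 reached 12.97 log2 units, and the labels name a check of surface markers but no sort. Exchanging ND 1-month replicate 1 with ND 2-month replicate 3 raised the within-group correlation most of 135 exchanges, from 0.968 to 0.977, and ranked 4 after the macrophage score was removed, so a mislabelling and the mixture cannot be told apart for these arrays by values alone. Animals that differ stay open, as untested.

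The second pattern is the 552 probe sets called at 2 months, the comparison in which macrophage and cell cycle lists were also lower. With the macrophage score in the fit they kept a median 0.942 of their log2 fold change (quartiles 0.861 and 1.03), and 316 of them were still called. With the cell cycle score they kept 0.943 (0.855 to 1.03), and 99 were still called, the standard error growing by a median factor of 1.12. A probe set passes more easily with a small spread within groups. Those that follow either score within groups were thus less likely to be among the 552. The shares kept were partly fixed by that selection and do not decide whether either score is the whole cause. The beta-actin difference was -0.01 ± 0.05 (SE) between these groups, so the fit with it, which kept 1.00 (0.996 to 1.01), had nothing to remove and leaves RNA quality undecided; a direct effect of diet on stromal cells stays a hypothesis, as do unrecorded differences between culture or scan batches.

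The third pattern is the 612 small changes in the average over feeding times. After quantile normalization they kept a median 0.876 of their log2 fold change (0.798 to 0.969), and 246 were still called. With the beta-actin difference in the fit they kept 0.962 (0.897 to 1.03) while the standard error grew by a median factor of 1.12, and 42 were still called. The macrophage score differed by 0.03 ± 0.65 (SE) between the diets in this average, so the 1.00 kept with it was fixed beforehand and leaves macrophage content undecided. The 0.876 kept argues against the intensity distribution as the whole cause, but quantile normalization moved the share of higher calls from 35.1% to 57.0%. RNA quality stays open, since the 612 were selected in the fit without the beta-actin difference and GAPDH was not tested. With the cell cycle score in the fit 29 probe sets passed in the average, and what the 612 kept was not computed. Lower proliferation thus stays open, as do a diet effect and a batch that the labels do not record.

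Other splits of the same arrays were fitted for each comparison. For the average, 1 of 100 splits within feeding times, the real one, gave as many as 612 probe sets, the highest other giving 280. The real count was thus the highest of the 100, but leaving out 1 array lowered it to as few as 117, below that 280. For the F test all 100 splits gave at least the real 0, and the highest other gave 1022, the next 18. For the mean correlation between feeding times 21 of 100 splits gave at least the real 0.106, up to 0.314, so chance is not excluded. Groups of 3 against 3 make 10 splits, too few for a share under 0.05. At 2 months 1 of 10 reached the real 552, the highest other giving 0. At 1 month 10 of 10 reached the real 0 and another reached 32, at 4 months 10 of 10 and another reached 178. The split with 32 set ND replicates 1 and 2 and HFD replicate 2 against the others, and that with 178 set ND replicates 1 and 3 and HFD replicate 3 against the others. Whether these splits and that with 1022 follow a structure of the samples apart from diet was not tested. For 4 minus 1 month in ND and in HFD 10 of 10 splits gave the real 0, and the highest other was 0. For 2 minus 1 month in HFD 1 of 10 reached the real 17 (highest other 1), and for 4 minus 2 months 1 of 10 the real 153 (highest other 0).

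The numbers of called lists were compared with the same splits. In the average over feeding times 94 of 100 splits called at least the real 4 lists, up to 16, so chance is not excluded. The other comparisons again have 10 splits each, too few for a share under 0.05. Of these 7 reached the real 7 at 1 month (highest other 13), 1 the real 15 at 2 months (13) and 9 the real 4 at 4 months (11). For 4 minus 1 month 3 reached the real 14 in ND (17) and 2 the real 14 in HFD (16). Within HFD 8 reached the real 7 for 2 minus 1 month (13) and 1 the real 15 for 4 minus 2 months (12).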

How the results depend on the processing

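The macrophage covariate, the shifted column as deposited, the omission of 2 doubtful arrays together and that of probe sets missing on the shifted array were chosen after seeing the data; the other settings were planned. Counts are of probe sets unless lists are named. Where a cause is not shown by the setting's own construction, the cause was not tested.

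With the replicate number as a block, 320 passed at 2 months (310 shared with the 552) and 350 in the average (330 shared with the 612). Fitting only the arrays compared left 4 residual degrees of freedom and gave 2 at 2 months and 1 for 4 minus 1 month in HFD. The trend and robust variance model gave 1 at 1 month, the stricter filter 14, and leaving out cross-hybridizing probe sets 1. Array weights gave 28 at 1 month, 4330 at 2 months, 3317 in the average, 115 by F and 434 for 4 minus 1 month in HFD. In the average, quantile normalization gave 286 (246 shared), averaging per gene 261 genes against 460, and a minimum of 1.5-fold 101. The macrophage covariate gave 34 at 1 month and 1305 in the average. The shifted column as deposited gave 0 at 2 months and 0 in the average, since that array then matches no other. Without both doubtful arrays 1319 passed at 2 months, 268 in the average and 139 for 4 minus 1 month in ND.

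Of the 7, 15 and 4 lists called at 1, 2 and 4 months, an estimated correlation called 0, 0 and 0, and fry 0, 5 and 0; those 5 were interferon, cholesterol, skeletal muscle, fatty acid synthesis and adipogenic genes. No intensity filter gave 1 list at 1 month and 1 at 4 months, and quantile normalization 2 and 2. The macrophage covariate gave 7 lists at 2 months and 2 at 4 months, the shifted column as deposited 3 at 1 month, and the omission of both doubtful arrays 4 at 1 month and 2 at 4 months. Leaving out the probe sets missing on the shifted array gave 1 probe set at 1 month, and 3 lists at 1 month and 1 at 4 months. At 4 months those probe sets have values on all arrays compared, so there the setting shortens the lists and tests no gap.

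Leaving out each array in turn gave 0 to 2 probe sets at 1 month, 48 to 1261 at 2 months, 0 to 1 at 4 months, 117 to 1053 in the average, 0 to 32 by F, 0 to 1 for 4 minus 1 month in ND and 0 to 2 in HFD. Lists called ranged from 4 to 9 at 1 month (4 without ND 1-month replicate 1 or 2 or HFD 1-month replicate 2), 9 to 15 at 2 months (9 without ND 2-month replicate 1) and 2 to 6 at 4 months (2 without ND 1-month replicate 1 or HFD 4-month replicate 2), and the mean correlation between feeding times from 0.030 to 0.177.

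For single genes, the 84 passing values were recomputed under 2481 alternatives, of which 795 lost the call and 0 changed direction. The shifted column as deposited, where none passed, is not among these. The 0 was partly fixed beforehand. In all 552 probe sets called at 2 months the 3 HFD arrays lay beyond the 3 ND arrays, so leaving out 1 array could not reverse the sign. Among the alternatives counted, Sfrp1, Cxcl12, Hp, C1s and Psmb9 at 2 months lost the call when the compared arrays were fitted alone and in no other. Enpp1, Serpinb6b, Vegfd and Pdxdc1 in the average lost it in none. A fit of the compared arrays alone does not exist for the average, which takes all 18 arrays, so these genes did not face it. Of 2323 alternatives for the 79 values that did not pass, 85 passed, and 1 changed direction: Cd14 at 1 month was -0.13 with the macrophage covariate against 1.40. Cd14 belongs to the macrophage list, but it has no value on ND 1-month replicate 1 and so is not among the genes of the covariate. The 6 genes named by the F test passed in 10 of 173 alternatives. The dimmest tested probe sets lay just above 9.34 in linear intensity, and the deposited table holds no detection calls that would tell their signal from background.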

Other observations

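The comparisons within HFD described here, and the lists described in them, were chosen only after the 2-month result was seen, and they share the HFD 2-month arrays with it. From 1 to 2 months on HFD, 17 probe sets passed in limma, 6 higher and 11 lower. Sfrp1 fell by 3.03 ± 0.47 log2 units (SE, n = 3 per group, adjusted p = 0.0395), Cxcl12 fell by 2.94 ± 0.47 (0.0395), and Hp fell by 2.82 ± 0.46 (0.0395). The complement protease C1s fell by 2.17 ± 0.37 (0.0489), and C1r fell by 1.04 ± 0.16 (0.0395). The galectin Lgals9 fell by 2.06 ± 0.30, while the transcription factor Foxq1 rose by 0.67 ± 0.11. The 17 dropped to 0 with the replicate block, in a fit of the compared arrays alone, with the shifted column as deposited and without ND 1-month replicate 1, HFD 1-month replicates 2 or 3, ND 2-month replicate 1, HFD 2-month replicate 1 or HFD 4-month replicates 1 or 2. It was 1 to 6 without HFD 1-month replicate 1, ND 1-month replicates 2 or 3, HFD 2-month replicate 2, ND 4-month replicates 1 or 3 or HFD 4-month replicate 3, 182 without HFD 2-month replicate 3, 11 with the stricter filter, 67 with the macrophage covariate and 558 with array weights. All 20 cholesterol genes had negative values, with 0 passing and 17 falling adjusted over the list alone (median -0.75, adjusted p = 6.09e-18; adjusted p = 0.187 with an estimated correlation), Msmo1 standing at -0.86 ± 0.20. Fatty acid synthesis (17 of 21 negative, median -0.51, adjusted p = 1.62e-07; adjusted p = 0.187 with an estimated correlation), with Fasn at -0.65 ± 0.14, and the cell cycle list (48 of 48, median -0.75, adjusted p = 3.11e-16; adjusted p = 0.549 with an estimated correlation) were called lower too, beside macrophage markers at a median of -1.09 (adjusted p = 0.00308; adjusted p = 0.79 with an estimated correlation). With the macrophage covariate all 6 other called lists were still called.

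From 2 to 4 months on HFD, 153 probe sets passed, 63 higher and 90 lower, and several genes called at 2 months changed the other way. Sfrp1 rose by 2.70 ± 0.47 (SE, n = 3 per group, adjusted p = 0.0275), C1s by 2.66 ± 0.37 (0.0188), Lbp by 3.51 ± 0.51 (0.0188), Il1rn by 3.02 ± 0.55 (0.033) and Apln by 4.06 ± 0.82 (0.0419). Nrg1 fell by 3.16 ± 0.58 (-1.69 with its probe sets averaged), Fhl1 by 2.90 ± 0.56, Casq2 fell by 2.74 ± 0.40 and the leucine-rich repeat protein Lrrc15 by 2.46 ± 0.39. Interferon response genes had 22 of 26 positive values, with Psmb9 rising 2.82-fold, 25 not passing and 8 rising adjusted over the list alone (median 0.46, adjusted p = 1.61e-06; adjusted p = 0.463 with an estimated correlation; fry adjusted p = 0.0237). Of 21 hypoxia targets Ero1a rose by 1.44 ± 0.24 and 20 did not pass, 3 rising adjusted over the list alone (median 0.77, adjusted p = 1.61e-06; adjusted p = 0.555 with an estimated correlation). Of 20 adipogenic genes Cebpd rose 2.82-fold and 19 did not pass (median 0.35, adjusted p = 0.0166; adjusted p = 0.555 with an estimated correlation). Macrophage markers stood at a median of 2.50 (28 of 29 positive, adjusted p = 1.12e-08; adjusted p = 0.555 with an estimated correlation). The 153 dropped to 0 without HFD 2-month replicate 1 or HFD 4-month replicate 2, to 1 without HFD 2-month replicate 2 or HFD 4-month replicate 1, to 28 without HFD 4-month replicate 3 and to 5 with the macrophage score as a covariate; it was 0 with the shifted column as deposited, 43 with the replicate block, 99 without cross-hybridizing probe sets, 255 with quantile normalization, 303 in a fit of the compared arrays alone, 1073 without HFD 2-month replicate 3 and 3213 with array weights. Without other arrays it was 44 and 96 (HFD 1-month replicates 3 and 1), 241 (HFD 1-month replicate 2), 62 (ND 4-month replicate 1) and 69 and 89 (ND 2-month replicates 2 and 3). The 7 lists called from 1 to 2 months and the 15 called from 2 to 4 months kept the sign of their median under quantile normalization and median centring. With the macrophage covariate 5 of the 14 other than the macrophage list were still called, while hypoxia targets had a median of 0.10 (adjusted p = 0.122).

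Of the 36 tested lists 15 were called in none of the 4 diet comparisons. They include mesenchymal stromal cell surface markers (lowest adjusted p = 0.652), cyclin-dependent kinase inhibitors and senescence regulators (0.287), NF-kB and inflammatory genes (0.409), WNT pathway genes (0.355), haematopoietic niche factors (0.348) and osteoclast markers (0.429). Members of such lists could still pass: Cxcl12 and Angpt1 of the niche list and Sfrp1 of the WNT list fell at 2 months, while Spp1 of the niche list stood higher without passing. Over the niche genes with a value on every array, the mean relative level at 2 months was 0.28 ± 0.42 (SD, n = 3) in ND and -0.72 ± 0.20 in HFD.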
